A study of Arabidopsis thaliana with 12 samples.

How the data were processed

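RNA from *Arabidopsis thaliana* plants of the Columbia 0 ecotype was compared between the *psae1* mutant and the wild type (WT). PSAE1 encodes a subunit of photosystem I, and PSAE2 is its paralogue. Per the labels there were 12 samples, 6 WT and 6 *psae1*, numbered 1 to 6 in each genotype. The deposited table held a linear intensity for each of 3439 probes in each sample. What the authors did to background and scale was not given in the sources used here, nor were the scanner and the array layout. From the values, no intensity was negative, the mean per sample lay near 1, and 119 probes were at 0 in all 12 samples. In the *psae1* columns 9 values lay within 1e-06 of 100, and none did in the WT columns. The number of arrays limits the precision, and no counts lie behind the values.

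Intensities were converted to log2, with 0 taken as missing. The medians of the columns differed by 0.32 on the log2 scale, above the 0.1 set before the data were examined, so each column was centred on its median. Values of *psae1* minus WT are therefore relative to the median probe, which was 0.24 lower in *psae1* on the log2 scale before centring. A probe was tested where at least 3 values per genotype were measured, which held for 3279 probes. Tests used lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

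Probes were named through the platform annotation and a gene table of the TAIR10.1 assembly, used for names alone, since no build is named with the values. There were 692 probes with 1 gene, 870 with several and 1877 not listed, and 690 of the single-gene probes matched a locus. Genes were named from single-gene probes only. The rule for named genes took PSAE1 and PSAE2, the 10 largest rises and the 10 largest falls among single-gene probes past the threshold with a value in all 12 samples, and up to 4 members of each of 17 gene lists. No single-gene probe was named PSAE1 or PSAE2, so the level of the mutated gene, as a check of the labels, was not analysed here. Of 311 list genes 14 could be tested. Photosystem I, photosystem II, light-harvesting proteins, the Calvin cycle, tetrapyrrole synthesis, the plastid ribosome, and antioxidants and photoprotection each had 1 or more tested members. The lists for electron carriers and ATP synthase, plastid chaperones and proteases, protein import and thylakoid targeting, starch metabolism, photorespiration, nitrogen and sulfur assimilation, jasmonate and defence, flavonoid synthesis, other-tissue markers and cytosolic reference genes had 0. No list reached the 5 tested genes a list test required, so the planned list tests were not run. The 14 tested members were joined into 1 set after this was seen, and tested with camera (preset correlation 0.01, and an estimated correlation).

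Nothing in the labels says that samples of a genotype came from separate plants or cultures, so p-values measure the spread between these samples, which may be technical. Deviations from the genotype mean were correlated across 3257 probes, which are not independent replicates. Numbers 1 and 2, 3 and 4, and 5 and 6 of a genotype deviated together, with a mean r of 0.49 in WT and 0.47 in *psae1*. The other combinations had a mean r of −0.36 in each genotype. That value is no separate evidence, because deviations from a genotype mean cancel out and the r within pairs largely sets it. Of the 15 ways to put 6 numbers into pairs, putting 1 with 2, 3 with 4 and 5 with 6 ranked 1 in both genotypes. The median absolute difference was 0.085 within such a pair and 0.156 between pairs in WT, and 0.095 and 0.201 in *psae1*. The values were not identical, so the 12 samples were kept as separate by the rule set before the data were examined, and the fit of 3 averages against 3 was run beside them, as also set then. Counts and calls from it are printed beside those from 12 samples. Equal numbers also deviated together across the genotypes, with r of 0.33, 0.32, 0.33, 0.42, 0.25 and 0.23 for numbers 1 to 6. By these values the numbers pair the samples, on the evidence of the data and not of the labels. The sizes, errors and p-values given are nevertheless those of the fit without a replicate block, as set before the data were examined, except where the block is named.

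The procedure was tested on simulated data with 200 of 3257 probes changed, in which array and reading spread were taken from the data and 2 readings shared an array. Over 5 draws, the fit of 12 samples recovered a median of 87% of changes of 1.5-fold and 98% of changes of 2-fold, with 128 wrong calls. The averaged fit recovered 62% and 94%, with 7 wrong calls. With nothing changed, the fit of 12 samples made a median of 35 calls and at most 73, and the averaged fit made 0. These data left out the spread that equal numbers share across the genotypes. In a second simulation, added after seeing the data, equal numbers shared 39% of the reading spread and 20% of the array spread (variance, from the data), which gave a mean r of 0.28 between equal numbers, against 0.31 in the real values. Wrong calls were then 61 with 12 samples, 123 with 12 samples and the replicate block, 4 with averages and 7 with averages and the block. With nothing changed, medians of 17, 42, 0 and 0 calls were made, and at most 24, 50, 0 and 1. If the paired numbers are readings of 1 array, the adjusted p from 12 samples is thus too small. Both simulations drew the spread of each probe independently. The real differences between WT averages correlated between consecutive probe numbers (Spearman rho at least 0.33). The simulated numbers of wrong calls therefore need not hold for the real values.

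Set before the data were examined, other settings were quantile and cyclic loess normalization, values as deposited, omission of the dimmest 25% of probes, probes measured in all samples, a replicate block, averages of numbers (1 and 2, 3 and 4, 5 and 6, or 1 and 4, 2 and 5, 3 and 6), array weights, a trended robust prior, and omission of each sample. Added after seeing the data were averages with a replicate block, a random block, omission of numbers 5 and 6, removal of a running median of 51 probes along probe number, omission of probes beside bright probes, combinations of these, and omission of each pair of numbers.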

Results

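Expression was measured on arrays with 3439 probes in 6 WT and 6 *psae1* samples. The summed intensity per sample ran from 3611 to 3678 in WT and from 3436 to 3564 in *psae1*. The number of probes at 0 was 139 to 145 in WT and 153 to 168 in *psae1*. The comparison asks which transcripts differ in level in the mutant of PSAE1, a gene for a photosystem I subunit. The level of PSAE1 itself was not analysed here, so the genotype labels were not checked on the mutated gene.

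PSAN, a subunit of photosystem I, rose in *psae1* by 0.52 ± 0.07 on the log2 scale (SE, n = 6 per genotype, limma adjusted p = 0.00015). It was higher in 6 of 6 same-numbered comparisons, which come down to 3 of 3 when numbers that deviated together are averaged. LHB1B2, a light-harvesting protein of photosystem II, rose by 0.51, and the photosystem II subunit PSBY rose by 0.49. Without centring they were at 0.26 and 0.24, and LHB1B2 was at 0.07 after quantile and 0.08 after cyclic loess normalization. The 30 brightest probes had a median of 0.52, and LHB1B2, at a level percentile of 99.4, rose by about as much. PSAN and PSBY lay at level percentiles of 97.9 and 90.1. Of the 328 probes in the brightest 10%, 153 were called higher and 22 lower, with a median of 0.23. These single genes were not tested against probes of like level. Over all 6 numbers the deepest named falls were AT5G05330, at −1.75 ± 0.34, AT1G29040, at −1.31 ± 0.31, and AT4G22830, at −1.13 ± 0.11 (SE, n = 6, limma adjusted p = 0.0030, 0.0084 and 2.3e-05). The first 2 split by number, with AT5G05330 at −2.60 in numbers 1, 3 and 5 and −0.89 in 2, 4 and 6, and AT1G29040 at −1.76 and −0.85, while AT4G22830 was at −1.15 and −1.11. Averaging numbers in pairs hides this split, and in 2, 4 and 6 AT4G22830 lay lowest of the 3. AT-HF, an enzyme of histidine synthesis, fell by 0.68 ± 0.10 (adjusted p = 0.00036). With numbers averaged in pairs, PSAN and AT-HF passed narrowly (limma adjusted p = 0.043 each). AT5G05330, AT1G29040 and AT4G22830 also passed (limma adjusted p = 0.0012, 0.026 and 0.0047), and LHB1B2 and PSBY did not (0.055 and 0.074). PSAN was at 0.28 without centring, 0.22 after quantile and 0.21 after cyclic loess normalization, and lost its call in averages without centring or after quantile normalization, and in averages with the replicate block without numbers 1 and 2 or 3 and 4 (limma adjusted p = 0.089, 0.36, 0.20 and 0.22). With a random block for the pairs of numbers, AT5G05330 and AT1G29040 lost their calls (limma adjusted p = 0.23 and 0.26), AT-HF did so in averages with the replicate block without numbers 1 and 2 (adjusted p = 0.087), and LHB1B2 did not pass after quantile or cyclic loess normalization.

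Of 3279 tested probes 748 changed, 391 higher and 357 lower in *psae1*, with 1194 at an unadjusted p under 0.05. With numbers 1 and 2, 3 and 4, and 5 and 6 averaged, 76 changed, 38 higher and 38 lower, and 73 of these were among the 748. On simulated data in which paired numbers shared an array, the fit of 12 samples made 128 wrong calls and the averaged fit 7. Where equal numbers of the 2 genotypes also shared part of the spread these were 61 and 4, and 123 and 7 with the replicate block. The simulated probes were independent of each other, unlike the real ones, so these counts need not hold for the real values. Adding the replicate block to the averages of the real values gave 206, of which 196 were among the 748. Without centring, 1745 changed, 111 higher and 1634 lower, so the share of higher calls was 6.36% in place of 52.3%. Most changes were small, since 86.4% of the 748 were under 1.5-fold, while 3 rises and 18 falls reached 2-fold. Of these falls 9 had a 0 in 1 or more *psae1* samples, left out as missing, so their sizes rest on the samples above 0. Single-gene probes made up 137 of the 748, 67 higher and 70 lower, and 10 of the 76.

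The plot of named genes shows the rises and falls chosen by rule. AT3G09850 rose by 0.68 ± 0.09 when centred (adjusted p = 0.00016). Its deposited intensity was 35.6 ± 1.73 in WT and 48.2 ± 5.83 in *psae1* (SD, n = 6 each), a difference of 0.43 on the log2 scale without centring. It passed with averaged numbers (limma adjusted p = 0.020), and did not pass after quantile or cyclic loess normalization, at 0.16 and 0.18. AT4G32060 rose by 0.56 ± 0.05 (adjusted p = 1.3e-05), and passed when averaged (adjusted p = 0.032). It lost its call in averages after quantile normalization or without centring (adjusted p = 0.13 and 0.066), and in averages with the replicate block without numbers 1 and 2 or 3 and 4 (adjusted p = 0.20 and 0.22). HEMA3, a form of glutamyl-tRNA reductase in tetrapyrrole synthesis that was not in the fixed lists, rose by 0.60 ± 0.09. The other rises were AT2G40980 and AT2G26110, both by 0.60, AT1G62250 by 0.59, AT5G14910 by 0.57, and AT1G24240 and AT4G33540, both by 0.54. Without centring AT4G32060 was at 0.31, and HEMA3 and these 6 lay from 0.29 to 0.36. HEMA3 and these 6 did not pass when numbers were averaged. AT1G62250 also failed after quantile and cyclic loess normalization, AT2G40980 after quantile normalization, and AT1G24240 with the random block. AT5G14910 also failed with the random block, without numbers 5 and 6, and in averages with the replicate block (limma adjusted p = 0.068). It was lower in 1 of 6 same-numbered comparisons.

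**Figure D1:**
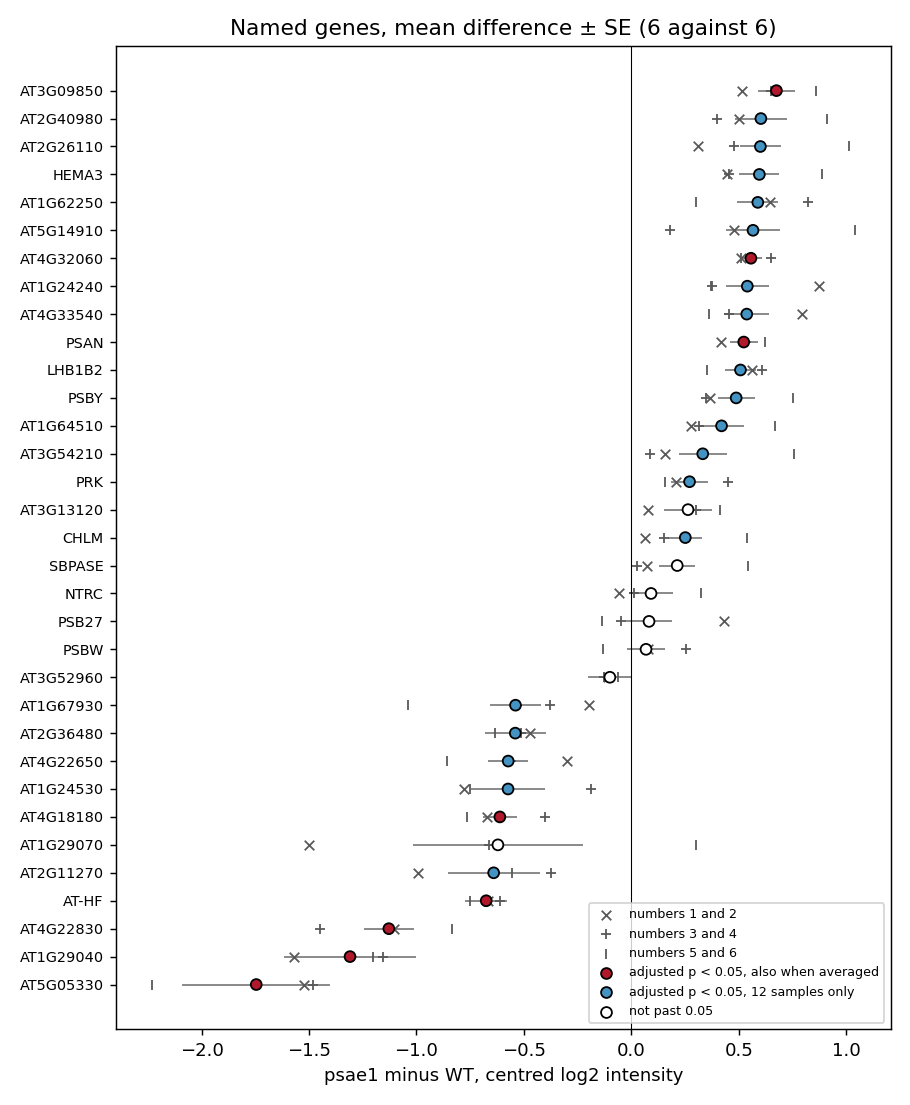
Difference of *psae1* minus WT in centred log2 intensity for each named gene (x axis), with circles and bars for the mean ± SE of 6 against 6 samples and small marks for the differences of numbers 1 and 2, 3 and 4, and 5 and 6 averaged. Red circles passed an adjusted p of 0.05 in both fits, blue circles only with 12 samples, and open circles in neither; PSAN lies at 0.52 and AT5G05330 at −1.75.

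Among the falls, AT5G05330 had a deposited intensity of 0.329 ± 0.0454 in WT and 0.0983 ± 0.0604 in *psae1* (SD, n = 6 each). Its probe number adjoins that of AT3G09850, among the 30 brightest probes. AT4G22830 fell from 0.250 ± 0.0349 to 0.0962 ± 0.0144, and AT1G29040 from 0.149 ± 0.0300 to 0.0560 ± 0.0260 (SD, n = 6 each). These 3 probes lie in the dimmest 10% of the tested probes. AT4G18180 was brighter and fell by 0.61 ± 0.08 (adjusted p = 0.00015), and it passed when averaged (limma adjusted p = 0.042), but not in averages with the replicate block without numbers 1 and 2 (adjusted p = 0.19). AT2G11270 fell by 0.64, AT1G24530 and AT4G22650 both by 0.57, and AT2G36480 and AT1G67930 both by 0.54. These 5 did not pass when averaged. AT1G67930 was at −0.29 without numbers 5 and 6, and did not pass in averages with the replicate block (limma adjusted p = 0.078). AT2G11270 also lost its call after quantile or cyclic loess normalization. AT2G11270 and AT1G24530 lost their calls when single samples were left out. PRK, CHLM and AT3G54210, given with the lists, likewise lost their calls when some single samples were left out.

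Of the 14 tested list members 7 rose, 0 fell and 7 did not pass, and 9 were higher when adjusted over the list alone. After quantile normalization 3 were higher and 0 lower, after cyclic loess normalization and without centring 3 were higher and 1 lower. Leaving out 1 sample gave 4 to 7 higher and 0 lower, and leaving out numbers 5 and 6 gave 3 higher and 0 lower. Averages of numbers 1 and 4, 2 and 5, and 3 and 6 gave 5 higher and 1 lower. Averages with the replicate block gave 3 higher and 1 lower without numbers 5 and 6. Such averages gave 0 either way without numbers 1 and 2 or 3 and 4, where 62 and 91 probes changed in all. In averages after quantile normalization or without centring limma also called 0 either way, of 57 and 682 changed probes in all. The median of the 14 members was 0.26, with 12 above 0 and 2 below. Joined into 1 set after the data were seen, they stood above the other probes by 0.25 (camera p = 0.00056, and p = 0.022 with an estimated correlation). With averaged numbers the p was 0.00095, and 0.072 with an estimated correlation, and with the replicate block it was 0.0017, and 0.085 with an estimated correlation. With drift along the probe numbers removed the height was 0.15 (camera p = 0.0037, and p = 0.051 with an estimated correlation). Camera compared the members with probes of all levels, and brighter probes were higher in *psae1* relative to the median probe. Random sets of probes matched on level had a median of 0.08 and a 95th percentile of 0.20, against 0.26 for the members.

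PSAN was the single tested member of the photosystem I list, and LHB1B2 that of the light-harvesting list. Of 3 photosystem II members PSBY rose, whereas the assembly factor PSB27 (0.08) and the subunit PSBW (0.07) did not pass and lay below 0 under quantile and cyclic loess normalization and without centring. After cyclic loess normalization PSBW was lower, at −0.38 (adjusted p = 0.0034). Of 2 Calvin cycle members PRK, phosphoribulokinase, rose by 0.27 (adjusted p = 0.036), and SBPASE, sedoheptulose bisphosphatase, was at 0.21 without passing. CHLM, a methyltransferase of chlorophyll synthesis, rose by 0.25 (adjusted p = 0.035). Without centring PRK was at 0.02, CHLM at 0.00 and SBPASE at −0.03, so their height is relative to the median probe. Neither PRK nor CHLM, nor the plastid ribosome gene AT3G54210, passed after quantile or cyclic loess normalization.

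In the plastid ribosome list, AT1G64510 rose by 0.42 (adjusted p = 0.012) and AT3G54210 by 0.33 (adjusted p = 0.044), while AT3G13120 (0.26) and AT1G29070 (−0.62 ± 0.40, SE) did not pass. AT1G29070 was at −0.20 without *psae1* 2, and at −0.16 in numbers 1, 3 and 5 and −1.08 in 2, 4 and 6. It passed as lower in averages of numbers 1 and 4, 2 and 5, and 3 and 6 (adjusted p = 0.04996), and, at −1.08, in averages with the replicate block without numbers 5 and 6 (adjusted p = 0.022). Without centring AT1G64510 was at 0.17 and AT3G54210 at 0.08, and neither passed (adjusted p = 0.14 and 0.50). Both also lost their calls without numbers 5 and 6, at 0.30 and 0.12, as did PRK and CHLM, and AT3G54210, at 0.14, PRK and CHLM did so with drift removed. With the replicate block, AT3G13120 passed (adjusted p = 0.028) but did not in averages with that block (adjusted p = 0.23), and AT3G54210 and CHLM no longer did (adjusted p = 0.060 and 0.063). Of 2 antioxidant members neither passed, with the thioredoxin reductase NTRC at 0.09 and the peroxiredoxin AT3G52960 at −0.10. Without centring, AT3G52960 was lower, at −0.35 (adjusted p = 0.018), and NTRC was at −0.16. Of the 7 list members that rose, PSAN alone passed when numbers were averaged, and PSAN, LHB1B2 and PSBY did when the block was added.

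Some probes without a single gene name, picked after their values were seen, also changed. Probe 1713 rose by 1.46 ± 0.12 and probe 1701 by 1.38 ± 0.10, neither with a gene listed. Both passed with 12 samples and with averaged numbers. Probes 2399 and 4466, each with 2 genes listed, were lower in *psae1*, but 2399 was listed at 0 in 1 and 4466 in 3 of the 6 *psae1* samples. Those values were left out as missing, so no size is given for these probes.

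**Figure D2:**
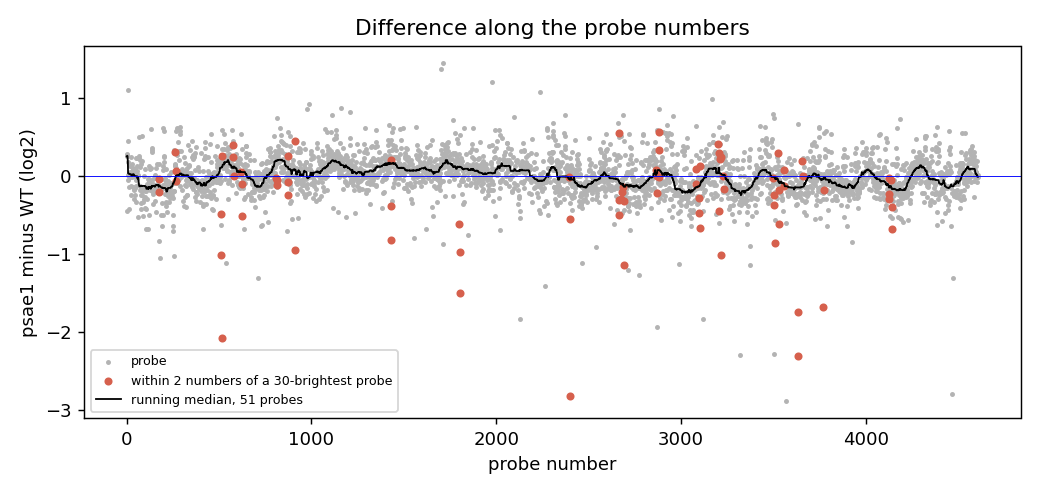
Difference of *psae1* minus WT (log2, y axis) for each tested probe along the probe numbers (x axis), with red points for probes within 2 numbers of the 30 brightest and a line for the running median of 51 probes. AT5G05330, at −1.75, lies beside a bright probe; values of 0 are left out of the differences drawn.

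**Figure D3:**
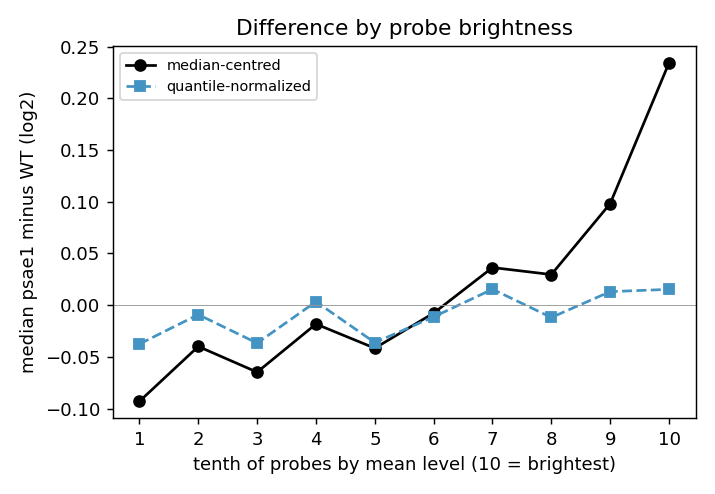
Median difference of *psae1* minus WT (log2, y axis) for probes ordered by mean level into 10 equal parts (x axis, 10 the brightest), with circles for median-centred and squares for quantile-normalized values. The brightest part lies at 0.23 when median-centred and at 0.02 when quantile-normalized. Centred values are relative to the median probe, which was at −0.24 before centring.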

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

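Samples were compared with the others of their genotype in 74 sets of 6 values, 2 of which held a sample far from the rest. Chance gives about 1 in 20 where the 6 values are independent, which paired numbers are not. A sample that deviates together with its paired number can escape this comparison. In the fit with array weights, *psae1* 5 and 6 had the lowest weights, 0.40 and 0.39, against 0.72 to 2.09 in the other samples. The summed intensity of WT 5 was 3678, against 3611 to 3631 in the other WT samples, a gap of 0.708 of the range. PRK, phosphoribulokinase, had a centred log2 intensity of 1.05 in *psae1* 3, against 0.52 to 0.70 in the other *psae1* samples, a gap of 0.671 of the range. Without *psae1* 3, PRK was at 0.20 (limma adjusted p = 0.051) and lost its call.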

How the results depend on the processing

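Removal of drift, omission of numbers 5 and 6 or of bright probes' neighbours, the random block, averages with a replicate block, averages after another scaling, omission of a pair of numbers, and the joined list were chosen after seeing the data. Averaging numbers 1 and 2, 3 and 4, and 5 and 6 gave 76 changed probes, 38 higher and 38 lower. Averaging 1 and 4, 2 and 5, and 3 and 6 leaves as few samples but gave 888, 466 higher and 422 lower. Each of these averages holds numbers that deviate together with numbers in the other averages, which narrows the spread between them. The 888 therefore cannot show whether fewer samples alone account for the 76. In the fit with a random block, the consensus correlation within the pairs 1 and 2, 3 and 4, and 5 and 6 was 0.71. With the replicate block on these averages, 206 changed, 117 higher and 89 lower. A random block for the same pairs gave 189, 135 higher and 54 lower. Values as deposited gave 1745, 111 higher and 1634 lower, and when averaged 17 higher and 665 lower. Averages after quantile normalization gave 57, 14 higher and 43 lower, and quantile normalization of 12 samples gave 243 higher. With drift removed, averages gave 175, 101 higher and 74 lower, and with the replicate block 461, 245 higher and 216 lower. Averages with the replicate block gave 62 without numbers 1 and 2, 23 higher and 39 lower, 91 without 3 and 4, 45 higher and 46 lower, and 445 without 5 and 6, 243 higher and 202 lower. An unadjusted p under 0.05 gave 1194, 616 higher and 578 lower, and a 2-fold minimum 21, 3 higher and 18 lower. Leaving out the centring lowers the difference of every probe measured in all samples by the same amount, which moves calls from higher to lower. Apart from this and the changed thresholds, the cause of these shifts was not tested. The other fits gave counts within 1.5 times of those reported. The replicate block with 12 samples gave 931 changed probes, within 1.5 times; among named genes it changed only the calls of AT3G13120, AT3G54210 and CHLM, and the call AT3G13120 gained was not there in averages with the block (adjusted p = 0.23). Leaving out each sample gave 610 to 761 changed, 327 to 394 higher and 274 to 367 lower, and a joined list shift of 0.20 to 0.29 with a camera p of at most 0.0012. The joined list kept its direction and its camera call in all alternatives run, but with drift removed its shift fell from 0.25 to 0.15; with an estimated correlation its p ranged from 0.0019 to 0.36.

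Of 26 named genes past the threshold none changed sign, 8 passed with averaged numbers and 20 with averages and the replicate block. Such averages with the block kept 5 without numbers 1 and 2, 10 without 3 and 4, and 19 without 5 and 6. Averages kept 5 after quantile normalization, 11 as deposited and 11 with drift removed, and the random block kept 15. The random block ended the calls of AT5G05330 (adjusted p = 0.23) and AT1G29040 (adjusted p = 0.26), which had passed when averaged. Of the 26 calls, 21 lasted through every omission of 1 sample, which says little about stability, since the sample that deviates with it stays in. AT2G11270 lost its call in 9 of the 12 omissions (adjusted p up to 0.096), AT3G54210 in 8 (0.090), PRK in 8 (0.073), CHLM in 6 (0.077) and AT1G24530 in 4 (0.059). Sign changes fell on 4 genes that had not passed. As deposited, SBPASE was at −0.034, NTRC at −0.16, PSB27 at −0.17 and PSBW at −0.18, with the same values when averaged. NTRC was at −0.024 without numbers 5 and 6, averaged or not, and at −0.059 with drift removed, averaged or not. PSB27 was at −0.13 after quantile and −0.12 after cyclic loess normalization, −0.067 with drift removed, and −0.093 in averages without numbers 1 and 2. PSBW was at −0.21 after quantile and −0.38 after cyclic loess normalization, and −0.026 in averages without numbers 3 and 4. The sign changes as deposited follow from leaving out the centring, which lowers each of these differences by the same amount. The cause of the other sign changes was not tested. The level of PSAE1 and the planned list tests gave no value, and averaging the probes of a gene changes nothing for the joined list, whose 14 members have 14 probes. Low signal limits the deepest falls, which lie among the dimmest probes.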

Other observations

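Listed at 0 in 5 or 6 *psae1* samples were 7 probes measured in 6 WT samples, and 4 of them lay within 2 numbers of a very bright probe. AT5G38360, which did not, was at 0 in all 6 *psae1* samples. It was dim in WT, at 0.055 to 0.091, against a median measured intensity of 0.60 to 0.62 per WT sample. At 0 in all 6 *psae1* samples there were 5 such probes, and no probe showed the reverse in all 6 samples. The reverse at 5 or 6 samples was not counted.

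In what follows, the tests of dim probes, of the constant background and of bright genes outside the lists were chosen only after the result was seen. The 81 probes within 2 numbers of the 30 brightest had a median difference of −0.13, with 22 called lower and 13 higher. Of the 18 called falls of 2-fold or more, 6 were in this group, AT5G05330 among them. Level-matched random sets of scattered probes held at most 4 such falls (share 1e-04, the smallest that 10000 sets can give). The 81 probes lie in runs of nearby numbers, whose differences correlate, so scattered sets may vary too little. The share therefore does not exclude a larger spread of dim probes. The median was −0.29 at a distance of 1 number, −0.05 at 2 and −0.07 at 3 to 4. Calls were 13 lower and 3 higher at 1, and 9 lower and 10 higher at 2. Local background taken from a bright neighbour may lower these probes. The test set beforehand, against neighbours of the next 30 bright probes, gave a difference of −0.054 with a share of random splits of 0.175, which its stated bound reads as evidence against this; that bound was wrong, because those neighbours also stand beside bright probes and a missed threshold does not show equality. Local background and a real fall of these genes cannot be told apart, since the spot layout was not used here.

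Differences of consecutive probe numbers correlated across probes (Spearman rho 0.32), while their levels hardly did (0.06). The place of a spot on the array is a candidate source, since the 3 differences between WT averages of numbers 1 and 2, 3 and 4, and 5 and 6, with no genotype in them, correlated by at least 0.33. Whether these averages are separate arrays was not established. Removing a running median left 776 changed probes, 548 of them among the 748, and lowered the joined list members' height above the other probes from 0.25 to 0.15 (camera p = 0.0037, and p = 0.051 with an estimated correlation). Running medians of the 3 differences of *psae1* minus WT averages were compared along the probe numbers. Numbers 1 and 2 correlated by 0.54 with 3 and 4 and by 0.15 with 5 and 6, and 3 and 4 by −0.14 with 5 and 6. The drift thus did not repeat alike in all 3, and a genotype effect on genes with neighbouring numbers was not tested separately.

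Relative to the median probe, brighter probes were higher in *psae1*, with a median of 0.23 in the brightest 10% and 0.10 in the ninth. The 30 brightest probes had a median of 0.52. The median probe itself was at −0.24 before centring, so a rise of bright probes cannot be told from a fall of dimmer ones. A constant background subtracted more in *psae1* does not account for the trend. The step between the ninth and the brightest part was 0.14, and a fitted offset gives 0.01. The listed photosynthesis and plastid genes may take part, as their median exceeded that of 99.3% of level-matched random sets, in a test written before its result was seen but on members joined after the data were seen. The tested members could not be the whole of it, since only 5 of the 328 brightest probes were among them. Without those 5 the median of the brightest 10% was still 0.23. The 47 bright single-gene probes outside the lists had a median of 0.18, with a bootstrap interval over probes, not arrays, from 0.09 to 0.26. Whether they include other photosynthesis or plastid genes was not tested. An unequal response of the arrays to brightness stays open, since quantile normalization removes the trend by construction (0.02 in the brightest 10%).

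Over 3257 probes with all values, the real split gave 741 changed probes, and among 100 drawn splits of the 12 samples it alone did so (1 of 100), the highest other giving 186. Of the 32 splits that part all 6 numbers, 1 gave as many, the real one, and the highest other gave 4, so single samples split by chance did not give as many. Because numbers 1 and 2, 3 and 4, and 5 and 6 deviate together, most of these splits part values that are not independent. Only 4 of the 32 keep those pairs together, too few for a share under 0.05, with 4 as the highest other count. With averaged numbers the 10 splits are too few for a share under 0.05; the real split gave 73 and the highest other 0. For the joined list, with the same limit, 1 of 100 splits gave a camera p as small, the real one at 0.00056, and the lowest other p was 0.00072.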
